A study of Homo sapiens
Mus musculus and Homo sapiens and Mus musculus with 79 samples.

How the data were processed

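The series measured RNA crosslinked by ultraviolet light to 1 tagged protein per library, by CLIP or by CLAP. Per the labels' protocols, CLIP captured the protein on an antibody against a V5 tag, whereas CLAP bound a covalent tag to a resin and washed it under denaturing conditions. The labels list 79 samples from HEK293T human kidney cells and from PSM33 mouse embryonic stem cells, inputs included. Plus-tag, minus-tag and no-mixing designs follow the labels. Minus-tag tables are read here as human RNA from mixtures whose human cells lacked the tagged protein, a reading the labels do not spell out. The word Gagnon in the SPEN library's label is not explained there.

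The tools named in the submitters' processing notes are Trim Galore 0.6.2, FastQC 0.11.8, Bowtie2, STAR and Picard. The builds named in those notes are hg38 (GRCh38) and mm10 (GRCm38). Which step each aligner served, and how samples labelled as replicates were combined, is not given in the sources used here. The authors deposited 36 tables, 30 human and 6 mouse, each for 1 capture library with its input. Every line is a 100-nt window of a gene's joined exons or joined introns, numbered along the gene, and the text takes the numbering to start at the 5′ end.

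Each table holds 4 values per window: a sample count, an input count, an enrichment and a p-value. The file headers name them except in PTBP1 and SAFA minus-tag CLAP, where the enrichment and p-value were identified from the numbers. The deposited counts are whole reads per window, and windows without sample or input reads are not listed. The authors' enrichment is a ratio of the sample count to the input count, times a constant that is the same for every window of a table. How that constant was set is not given in the sources used here. The deposited p-value is a binomial tail for more sample reads than observed, given the summed reads and that constant, and it is not adjusted for multiple tests. Input counts had been raised to a minimum per gene and region, so that 55.1% of listed windows in the CTCF table and 93.5% in the SAFA minus-tag CLAP table lie on that minimum.

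Folds given in the text were recomputed from the deposited counts and the constant in the authors' enrichment column. They are therefore on the authors' scale. The deposited p-values were adjusted per table by the Benjamini-Hochberg method. A window was called enriched at a fold of at least 3 and an adjusted p below 0.01, and a gene was called enriched if it held an enriched window. Shares of enriched windows carry exact 95% Clopper-Pearson intervals, and folds of single windows carry exact 95% intervals on the binomial share. These intervals cover counting error only, and neighbouring windows are not independent. A pair of libraries was called different where the intervals of their shares did not overlap.

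Each table holds 1 sample column, so no replicate check of any value was possible and no test between conditions was run. Fits with edgeR or DESeq2, a replicate block and leave-one-out fits were not possible for the same reason. Comparisons set plus-tag against minus-tag libraries, CLIP against CLAP, CLAP of each protein against CLAP of green fluorescent protein (GFP), and mixed against unmixed cultures. They also set Spy-tagged PTBP1 against the other Spy-tagged proteins, SPEN on its own, and the genes shared between proteins against the number chance gives.

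Comparisons, thresholds, gene lists and the naming rule were chosen before the data were examined. The rule named the 10 genes with the highest window fold per library, among enriched windows of at least 20 sample reads, and the listed genes. The 10 lists hold lncRNAs, small structured RNAs, PTBP1-regulated transcripts, splicing factor transcripts, mitochondrial transcripts, abundant cytoplasmic mRNAs, replication-dependent histone mRNAs, HOX and other developmental genes silenced by PRC2, the tagged proteins' own transcripts, and mouse embryonic stem cell markers. Silencing by PRC2 comes from the name of the HOX list and was not examined in the cells used. Its genes did have reads, such as 668 on HOXA3 in GFP plus-tag CLIP. Mouse members were matched by capitalised human symbols. No mitochondrial transcript was listed in any table, so that list is not analysed here. The stem cell markers were measured in the mouse tables.

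Between paired libraries, each list's genes with at least 20 reads were compared with all genes by the median log2 ratio of gene folds, after subtracting the median over all genes. Its percentile was taken among 10000 random lists matched on read depth, for lists of at least 5 measured members. Gene folds relative to the table totals divide a gene's fold by the mean fold of its table. Correlations across genes used genes of at least 50 reads, and genes are not independent replicates. The first 3000 nt of XIST exon space were compared with the rest. Human gene positions are from the RefSeq annotation on GRCh38.

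Alternatives were a fold of 2 or 5, an adjusted p below 0.05, an unadjusted p below 1e-06, at least 10 or 20 sample reads per window, and leaving out small structured and ribosomal genes. Others were thinning to the smallest total, a fold relative to the median window, and genes as the unit. Alternatives added after the data were seen were a fold relative to the table totals, a binomial tail that includes the observed count, windows of at least 20 input reads, and the chromosomes listed in full in a shortened table. The shortened table is EZH2 minus-tag CLIP, which stops partway and has no windows of XIST. The EED no-mixing library was matched to its table by elimination, since the labels tie the other EED samples to other tables.

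Summed sample reads over listed windows ran from 203527 in PTBP1 minus-tag CLAP to 47950000 in PSPC1 CLAP. On simulated windows of the EZH2 plus-tag CLAP table, 48.0% of windows raised 5-fold and 100% of windows raised 20-fold were called, and 0 unchanged windows were. Simulated EZH2 plus-tag CLIP gave 17% and 100%, and simulated GFP plus-tag CLAP 79.0% and 100%. The simulations set folds by the table totals and raised only windows of at least 5 expected sample reads. Their constant was 0.664 for EZH2 plus-tag CLAP, against 0.0885 on the authors' scale. They therefore do not give the recovery on the authors' scale or in windows of fewer reads. For PTBP1 and SAFA minus-tag CLIP the labels name a track over XIST but no window table, so those samples are left out. Calculations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, pyarrow 21.0.0 and matplotlib 3.10.9.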

Results

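RNA bound to chromatin proteins was read in 36 capture tables, 30 from human HEK293T cells and 6 from PSM33 mouse embryonic stem cells. EED, EZH2 and SUZ12, the core subunits of the histone methyltransferase complex PRC2, were each captured by CLIP and by CLAP, with and without the tag in the human cells. PTBP1 and SAFA (HNRNPU), both RNA-binding proteins, served beside them, and GFP was the protein not known to bind RNA. CLAP tables also cover CHTOP, CTCF, EWSR1, PSPC1, TET2, WDR5 and Halo-YY1, cultures of EED, EZH2 and SUZ12 cells without mixing, and in mouse cells SPEN and 5 Spy-tagged proteins. The labels give 1 or 2 samples per group, but each table has 1 sample column, so replicates cannot be told apart and no value has a replicate error. Summed sample reads were 13206064 in EED plus-tag CLIP and 1913669 in EED plus-tag CLAP. For EZH2 they were 9465685 and 2016552, for SUZ12 16043792 and 4143579, and for GFP 1723788 and 401241. PTBP1 plus-tag CLIP and CLAP held 35577759 and 34765996 reads, and those of SAFA 19754343 and 25668675.

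The number of RNA windows enriched over input differed widely between proteins. PSPC1, a paraspeckle protein, had 2762306 enriched windows, 92.3% of its listed windows, and EWSR1 had 825339 (26.2%). PTBP1 plus-tag CLAP reached 22.7%, SUZ12 plus-tag CLIP 13.3%, and SAFA plus-tag CLAP 12.6%. CHTOP, an mRNA export factor, had 9552 enriched windows in 2316 genes. Enriched windows made up at least 0.1% of the listed windows in 12 of the 36 tables. On the authors' scale no window was enriched in CTCF, WDR5, GFP CLAP, EED CLAP of any kind, or the EZH2 and SUZ12 no-mixing libraries. The highest fold was 0.754 in GFP CLAP and 1.26 in CTCF, so the cut of 3 was out of reach there. With folds set by the table totals, CTCF had 1627 enriched windows, WDR5 2349, GFP CLAP 34 and EED plus-tag CLAP 659. EED minus-tag and no-mixing CLAP then had 26 and 350, and EZH2 and SUZ12 no-mixing CLAP 1478 and 332. Intronic windows formed 93.6% of the enriched windows of PTBP1 plus-tag CLAP and 15.4% of those of EZH2 plus-tag CLIP. Introns held 84.1% and 79.5% of the input reads over listed windows of these libraries. The constant in the authors' enrichment ran from 0.0251 in GFP plus-tag CLAP to 17.1 in PSPC1 CLAP, and with folds set by the table totals 20 tables passed 0.1%. On that scale PSPC1 had 4.87%, EWSR1 4.81%, TET2 1.74% and SUZ12 plus-tag CLIP 1.13%. SAFA plus-tag CLAP had 0.802% and PTBP1 plus-tag CLAP 0.789%, so the order of the proteins depends on the constant.

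**Figure D1:**
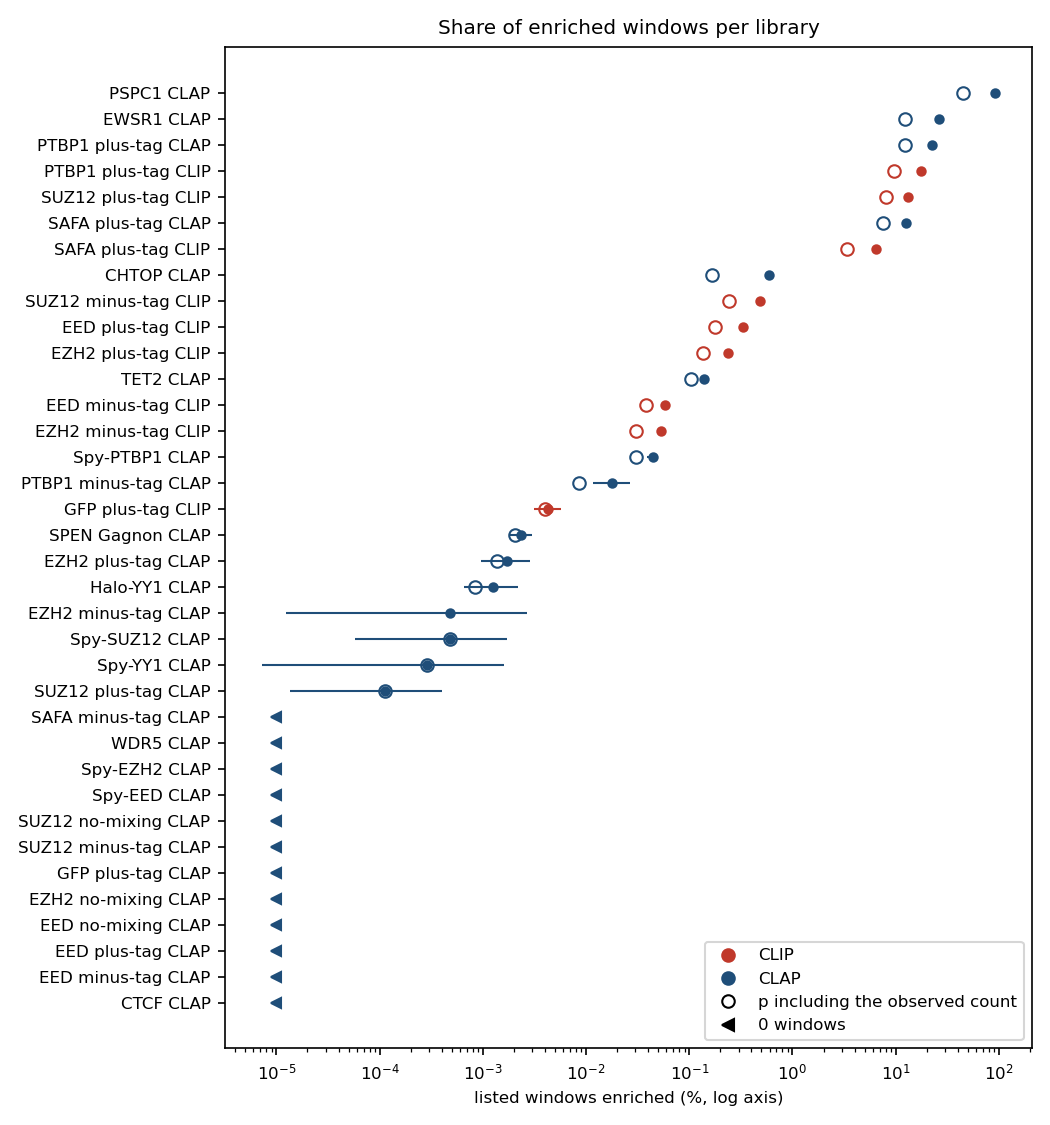
Share of listed windows called enriched in each table, in percent on a log axis, with CLIP in red and CLAP in blue, exact 95% intervals on filled points, and triangles at the left edge for tables with 0 enriched windows. Open points use a binomial tail that includes the observed count; PSPC1 falls from 92.3% to 44.9%, and the CLAP tables of EED, EZH2 and SUZ12 lie at or near 0.

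Plus-tag against minus-tag CLAP asks which human RNAs need the tagged protein for their capture. PTBP1 plus-tag CLAP held 1262395 enriched windows in 11821 genes, against 25 in 13 genes without the tag. SAFA plus-tag CLAP held 676407 in 11472 genes, against 0. Without the tag, 39022 of these PTBP1 windows and 79749 of these SAFA windows were listed, and the others could not be called there. The minus-tag libraries held 203527 sample reads for PTBP1 and 836673 for SAFA, against 34765996 and 25668675 with the tag. PTBP1 windows lay on PTBP2, its neuronal paralog, where 592 of 1022 windows were enriched with a best fold of 104. RTN4 had 833 of 1569 enriched windows, PKM 121 of 331, CLTA 101 of 214 and the lncRNA JPX 376 of 771. The highest PTBP1 folds were on DTL (481), SLC38A10 (471), SUZ12P1 (459, a pseudogene whose reads are uncertain), KMT2A (393) and NUP205 (382). Further high PTBP1 windows were on AFF4, EYA3, KMT2E, HBS1L and PHF20, with folds from 336 to 364.

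SAFA windows were highest on AEN, with a fold of 724, and on RPS19 (690), TPTEP2-CSNK1E (595), DDIT3 (530), ANAPC5 (468) and SNHG17 (457). BTG2 (424), PPP1R10 (424) and SESN2 (414) were also among its first genes. TPTEP2-CSNK1E overlaps CSNK1E and is uncertain. All 54 windows of the lncRNA NORAD and all 228 of the paraspeckle lncRNA NEAT1 were enriched for SAFA. All 127 windows of CHTOP and 369 of 390 windows of HOXC4 were enriched as well. Every measured splicing factor transcript (26 of 26) and abundant cytoplasmic mRNA (20 of 20) held an enriched window for both PTBP1 and SAFA. Of all measured genes, 11821 of 15279 did for PTBP1 and 11472 of 15049 for SAFA, so most genes did so in both. Of replication-dependent histone mRNAs, 8 of 9 did for SAFA and 1 of 9 for PTBP1. PTBP1-regulated transcripts did so in 13 of 13 cases for PTBP1 and in 13 of 14 for SAFA.

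For the PRC2 subunits, plus-tag CLAP had few enriched windows. EZH2 had 15, with 13 on the stress-induced chaperone HSPA6 (1:161524540-161526894; best fold 10.2, interval 3.96 to 37.6) and 2 on the co-chaperone STIP1 (7.12, interval 2.76 to 26.3). EZH2 minus-tag CLAP had 1, on PRDM15, and listed 2 of those 15 windows. SUZ12 plus-tag CLAP had 2, both on EML4 (2:42169353-42332548) and up to a fold of 24.8 (interval 9.58 to 91.5). Its minus-tag library had 0, but it listed 0 of these 2 windows. The same EML4 window, at exon position 2300 to 2400, reached a fold of 557 in PTBP1 minus-tag CLAP, where TOP2A reached 56.8. EED had no enriched window with or without the tag. Its highest listed genes in plus-tag CLAP were MEIS2 (1.77) and EZH2 (1.32), and MALAT1 reached 0.731 and XIST 0.536. In EZH2 plus-tag CLAP, EED reached 2.88, HSPA8 2.40, MEIS2 2.30 and HSP90AB1 2.00. No HOX or other listed developmental gene held an enriched window in plus-tag CLAP of EED, EZH2 or SUZ12, against 21 of 24 for PTBP1 and 22 of 24 for SAFA. Of all measured genes, 0 of 13983 did so for EED, 2 of 13520 for EZH2 and 1 of 14703 for SUZ12. For PTBP1 and SAFA, 11821 of 15279 and 11472 of 15049 did.

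Relative to all genes, abundant cytoplasmic mRNAs were higher in EZH2 plus-tag than in minus-tag CLAP in 20 of 20 cases, with a median log2 ratio of 2.49 above all genes and a percentile of 100 among random lists. SUZ12 had 19 of 20 such mRNAs higher with a median of 1.02, SAFA 19 of 20 with 1.82, and EED 3 of 20 with -0.32. Splicing factor transcripts were higher with the tag in 25 of 26 cases for SAFA, with a median of 1.67, and in 22 of 23 for PTBP1, with 0.71. The plus-tag share of enriched windows exceeded the minus-tag share for 2 of the 5 proteins, PTBP1 and SAFA. With folds set by the table totals it did so for all 5, among them EED at 0.0666% against 0.00509% and EZH2 at 0.205% against 0.0112%. The inputs differ too, with 52.3% of input reads in introns over listed windows for EZH2 with the tag and 39.2% without it. Depth differs as well, with 2016552 sample reads for EZH2 with the tag and 306207 without it. Gene folds sum only windows with sample reads, over inputs raised to a minimum. List ratios between such libraries therefore cannot be read as capture alone.

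**Figure D2:**
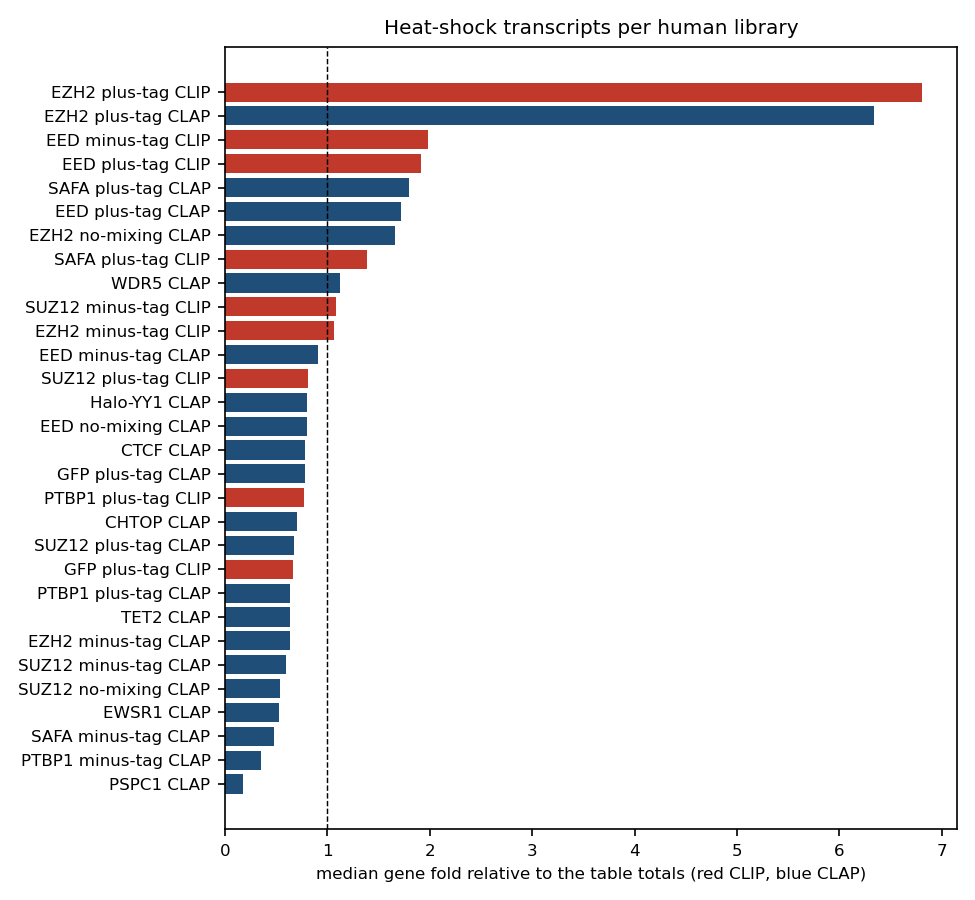
Median fold over input of heat-shock transcripts, relative to the table totals, in each of the 30 human tables (bars; dashed line at 1), with CLIP in red and CLAP in blue. EZH2 plus-tag CLIP (6.81) and CLAP (6.34) stand above all other tables, the next being EED minus-tag CLIP at 1.98; the genes were chosen after values of some of them were seen.

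Plus-tag against minus-tag CLIP asks the same of the antibody purification. Many windows were enriched with the tag, and the minus-tag libraries also held enriched windows, among them on the nuclear lncRNAs MALAT1 and NEAT1. EED plus-tag CLIP had 14082 enriched windows in 2346 genes, led by DUXAP9 (63.1) and DUXAP10 (56.6), paralogous pseudogenes whose reads are uncertain. HSP90AA1 (60.9), HMGN2 (59.3), ATXN2L (57.6), LENG8 (53.4; 19:54449199-54462016), SNRNP70 (50.6), PHYKPL (50.0) and KDM5C (44.6) followed. EED minus-tag CLIP had 1608 in 367 genes, on LENG8 (37.7), MALAT1 (34.8, interval 19.4 to 69.9), PABPN1 (32.7), XIST (31.9, interval 21.4 to 49.9) and NEAT1 (28.5). XIST, the lncRNA of X inactivation (X:73820656-73852714), had 100 of 320 enriched windows without the tag and 80 of 321 with it. NEAT1 had 108 of 228 without and 220 of 228 with the tag, and TUG1 6 of 126 and 54 of 127. MALAT1, a nuclear speckle lncRNA, had 73 of 90 and 72 of 92.

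EZH2 plus-tag CLIP had 7855 enriched windows in 1446 genes. The co-chaperone gene DNAJB1 reached 105 (19:14514769-14560391; interval 35.6 to 509), HSPH1 71.7, HSPA6 68.0, STIP1 60.9, FKBP4 57.5 and BAG3 48.1. LENG8 (56.5), CBX6 (48.1), KDM5C (41.7) and NUCB1 (41.5) completed its first genes. The EZH2 minus-tag table, which stops partway, had 517 in 148 genes, with STAU1 (34.7), LENG8 (33.3), SPTBN1 (27.1), SNRNP70 (25.0), NEAT1 (24.1) and MALAT1 (22.9) among the first. SUZ12 plus-tag CLIP had 537113 enriched windows in 11355 genes, with LENG8 at 401, CHTF18 at 373, RECQL4 at 342, SRRM2 at 319, CAPN15 at 312 and SCARNA2 at 282. CBS reached 505 there, a gene with a paralog and so uncertain. SUZ12 minus-tag CLIP had 9243 in 1937 genes, with MALAT1 at 75.5, LMNB1 at 58.0, LUC7L3 at 57.0, FTH1 at 52.8 and CALM3 at 51.7. KCNQ1OT1 had 488 of 764 and HOTAIR 37 of 103 enriched windows in SUZ12 plus-tag CLIP.

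Splicing factor transcripts held an enriched window in 25 of 26 cases for EED with the tag and 13 of 26 without. For EZH2 these counts were 23 of 26 and 7 of 19, and for SUZ12 26 of 26 in both. Of all measured genes, 2346 of 14704 did so for EED with the tag and 367 of 12442 without. EZH2 had 1446 of 14173 and 148 of 8261, and SUZ12 11355 of 15449 and 1937 of 12558. HOX and other listed developmental genes did so in 12 of 23 cases for EED with the tag, such as HOXD10 at 32.6 and HOXD9 at 23.4, and in 2 of 22 without. SUZ12 counted 24 of 24 with the tag and 8 of 22 without, and EZH2 7 of 24 and 1 of 16. Abundant cytoplasmic mRNAs did so in 15 of 20, 16 of 20 and 19 of 20 cases for EED, EZH2 and SUZ12 with the tag. The lncRNA list counted 8 of 15, 7 of 14 and 13 of 15. Of the tagged proteins' own transcripts, 10 of 12, 8 of 12 and 12 of 12 did. Relative to all genes, splicing factor transcripts were higher with the tag in 6 of 26 cases for EED, with a median log2 ratio of -0.63, and in 5 of 26 for SUZ12, with -0.56. Histone mRNAs were higher with the tag in 0 of 9 cases for EED and for SUZ12, with medians of -1.01 and -2.68.

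Of the 367 genes with enriched windows in EED minus-tag CLIP, 345 were also enriched with the tag, as were 1890 of 1937 for SUZ12 and 139 of 148 for EZH2. Independent lists would share 70.2, 1629 and 18.9 genes, so the ratios were 4.92 for EED, 1.16 for SUZ12 and 7.34 for EZH2. Each ratio is near the highest that the list sizes allow, so they cannot be ranked against each other. In the other direction, 9.53% of EED plus-tag enriched windows were enriched without the tag, and 5.53% for EZH2 and 0.915% for SUZ12, where 273750 of 537113 were listed without the tag. The share of enriched windows was higher with the tag for all 3 proteins, at 0.329% (0.324% to 0.335%) against 0.0580% (0.0552% to 0.0609%) for EED, 0.235% against 0.0536% for EZH2 and 13.3% against 0.483% for SUZ12. EED turned around with folds set by the table totals (0.129% against 0.229%), and EZH2 with at least 10 sample reads per window (29.1% against 33.6%). Among windows of at least 20 input reads, the SUZ12 intervals overlapped at 22.2% against 24.9%.

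CLIP against CLAP compares native antibody capture with denaturing covalent capture of the same protein. For the PRC2 subunits, windows enriched by CLIP were not called by CLAP on the authors' scale, except on HSPA6 and STIP1 for EZH2. Mean folds in plus-tag CLAP were 0.103 for EED, 0.133 for EZH2 and 0.224 for SUZ12. Only 0.00919%, 0.0120% and 0.00270% of their listed windows reached a fold of 3. A missing CLAP call thus does not show that an RNA was not captured by CLAP. Of 14082 EED CLIP windows 12596 were listed by CLAP and 0 enriched, and of 7855 EZH2 windows 7508 were listed and 15 enriched. Of 537113 SUZ12 CLIP windows 238231 were listed by CLAP and 0 enriched, and the others could not be called there. NEAT1 fell in this class, with best folds of 37.3 in EZH2 CLIP and 103 in SUZ12 CLIP, and so did MALAT1, with 67 of 88 and 75 of 87 enriched windows. HNRNPH1 was another, with best CLIP folds of 39.0 for EED, 40.8 for EZH2 and 85.5 for SUZ12. For PTBP1, 1053126 of 1083477 CLIP windows were listed by CLAP and 675155 (62.3%) enriched, and for SAFA 312625 of 315528 were listed and 229931 (72.9%) enriched. SLC38A10 and KMT2E were among the first 10 PTBP1 genes by both methods, with CLIP folds of 1204 and 1179. ODR4 (1212), USB1 (1014), RAD23B (944) and TMEM165 (910) were further PTBP1 CLIP genes. TPTEP2-CSNK1E, BTG2, DDIT3 and AEN were among the first SAFA genes by both, with CLIP folds of 566, 431, 396 and 389. THRAP3 (390), ATF4 (381) and RACK1 (336) were further SAFA CLIP genes. GFP CLIP had 44 enriched windows, on MALAT1 (11.4), EEF1A1 (10.4), NEAT1 (10.1) and XIST (3.17), and GFP CLAP had 0.

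Relative to all genes, splicing factor transcripts were higher in CLIP than in CLAP in 26 of 26 cases for EED (median log2 ratio 1.22), 25 of 26 for EZH2 (1.42) and 26 of 26 for SUZ12 (1.35). GFP gave 25 of 26 with 0.69, whereas PTBP1 gave 9 of 26 with -0.19 and SAFA 10 of 26 with -0.30. The first 4 lay at percentiles of at least 99.99 among random lists, PTBP1 at 36.2 and SAFA at 11.6. The median log2 ratio over all genes, subtracted here, was 3.59 for EED, 3.09 for EZH2 and 3.66 for SUZ12. HOX and other listed developmental genes were higher in CLIP in 13 of 19 cases for EED, 11 of 16 for EZH2 and 23 of 24 for PTBP1. The CLIP share of enriched windows exceeded the CLAP share for 4 of 6 proteins (EED, EZH2, SUZ12 and GFP), and the CLAP share was higher for PTBP1 (22.7% against 17.5%) and SAFA (12.6% against 6.37%). With folds set by the table totals, EZH2 turned around at 0.170% against 0.205% and GFP intervals overlapped. With genes as the unit PTBP1 turned around, and among windows of at least 20 input reads both PTBP1 and SAFA did.

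In CLIP of the PRC2 subunits and of GFP, XIST folds were higher over the first part of its exons than over the rest. In EED minus-tag CLIP the fold was 10.0 over the first 3000 nt of its exons and 3.03 after them, and in SUZ12 minus-tag CLIP 15.4 and 4.13, with peaks at position 700 to 800 in both. With the tag these values were 4.86 and 2.40 for EED, 6.26 and 2.85 for SUZ12 and 3.70 and 1.62 for EZH2. GFP CLIP gave 1.05 and 0.266, whereas PTBP1 CLIP gave 14.6 and 14.9 and SAFA CLIP 6.49 and 6.17. CLAP of EED gave 0.199 and 0.0396, of SUZ12 0.330 and 0.175, and of EZH2 0.142 and 0.0773, with 0 enriched windows each. The highest CLAP window of EED and SUZ12 lay at 800 to 900, as it did in the Halo-YY1 and TET2 tables at folds of 0.644 and 1.07. PTBP1 CLAP peaked at 12300 to 12400 with a fold of 70.2, and 105 of 193 exon windows were enriched. SAFA CLAP had 162 of 193 enriched exon windows, with folds of 3.90 over the first 3000 nt and 7.88 after them. TSIX overlaps XIST on the other strand, so reads without a strand call are uncertain.

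**Figure D3:**
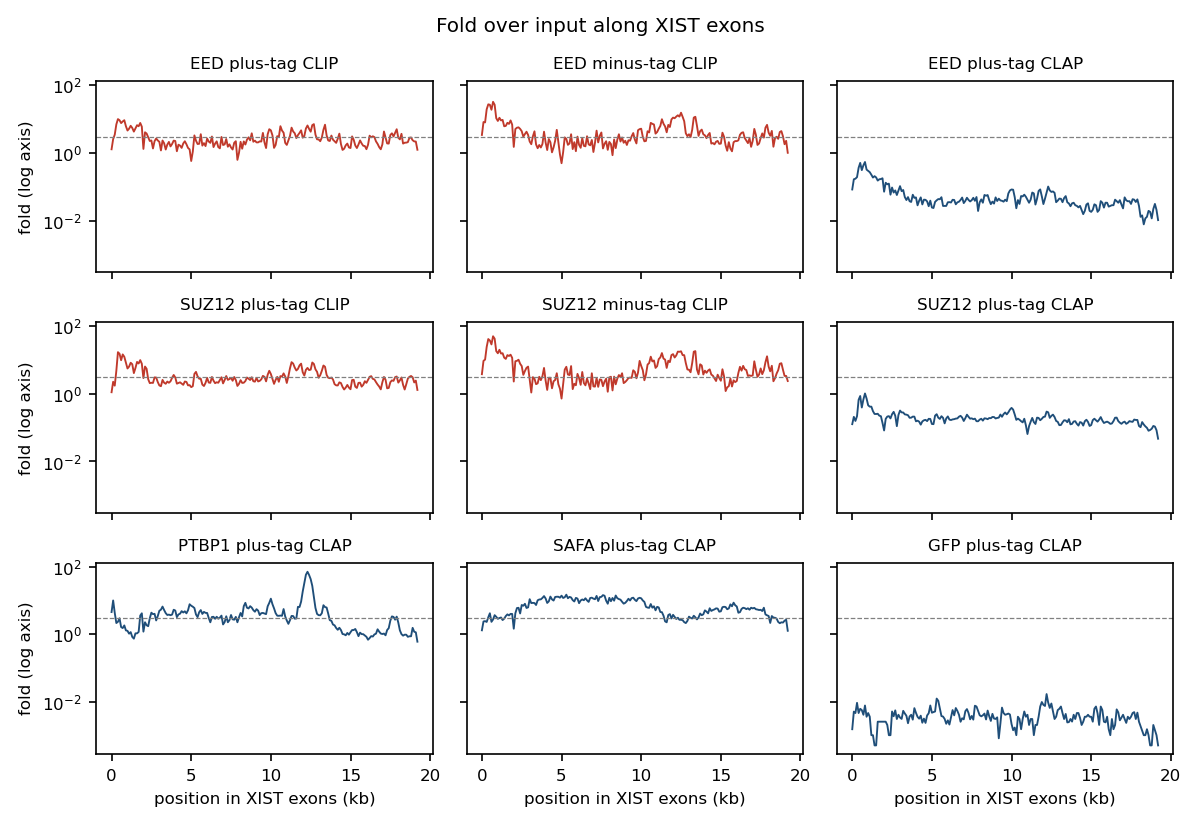
Fold over input (log axis; dashed line at 3) in 100-nt windows along XIST exon space for 9 human tables. EED and SUZ12 minus-tag CLIP are highest near position 700 (31.9 and 49.1), PTBP1 plus-tag CLAP near 12300 (70.2), and GFP plus-tag CLAP stays at or below 0.0174.

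CLAP of other proteins against GFP CLAP sets each capture beside a protein not known to bind RNA. PSPC1 windows were highest on NUP58 (7494), MIER1 (7126), KPNA5 (6484), BRWD1 (5270) and the splicing kinase gene CLK1 (3766, interval 2199 to 7081). PTBP2 had 852 of 1021 enriched PSPC1 windows, FAS 81 of 81 and NEAT1 139 of 215. EWSR1 windows were highest on ARF1 (1915), CLPTM1L (1196), AEN (758), CTBP1 (753) and LARP1 (720.5), with NEAT1 at 221 of 228 windows. CHTOP windows were highest on ZNF703 (84.8), KLC1 (75.1), RHOU (75.1), KHDRBS1 (65.4) and PTMA (63.0). TET2, a DNA demethylating enzyme, had 2299 enriched windows in 543 genes, with LPCAT1 at 235, CTBP1 at 57.6, ABCA3 at 53.0 and TET2 itself at 8.16. Halo-YY1 had 12, with 8 on DNAJB1 (4.73) and 4 on BAHD1 (5.25).

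Splicing factor transcripts held an enriched window in 25 of 25 cases for EWSR1, 26 of 26 for PSPC1, 7 of 25 for CHTOP and 1 of 26 for TET2. Of all measured genes, 14354 of 16565 did so for EWSR1, 14581 of 15348 for PSPC1, 2316 of 16243 for CHTOP and 543 of 16018 for TET2. HOX and other listed developmental genes did so in 24 of 24, 23 of 24 and 12 of 24 cases for EWSR1, PSPC1 and CHTOP. Small structured RNAs did so in 2 of 6 for PSPC1, 1 of 7 for EWSR1 and 0 of 7 for CHTOP. Relative to all genes, splicing factor transcripts were higher than in GFP CLAP in 25 of 26 cases for SAFA (median log2 ratio 1.76) and in 21 of 26 for PTBP1 (1.09). They were higher in 5 of 26 cases for CHTOP (-0.36), 2 of 26 for TET2 (-0.52) and 1 of 26 for Halo-YY1 (-0.71). These folds rest on different inputs, with 554432 input reads over listed windows for GFP and 18701674 for CHTOP, 39.6% and 24.7% of them intronic, so they differ by input as well as by capture. The share of enriched windows was above that of GFP for 6 of 12 proteins: PSPC1, EWSR1, PTBP1, SAFA, CHTOP and TET2. It was above GFP for 11 with folds set by the table totals, where SUZ12 lay below it (0.00320% against 0.0132%), and among windows of at least 20 input reads CHTOP and TET2 overlapped GFP. Of PSPC1 enriched windows, 49.6% held 1 or 2 sample reads, and with a tail that includes the observed count its share was 44.9%.

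Mixed against unmixed CLAP asks whether adding mouse cells altered what was captured from tagged human cells. EZH2 differed, through its windows on HSPA6 and STIP1, of which 2 of 15 were listed in the no-mixing table and 0 enriched; the others could not be called there. EED and SUZ12 no-mixing libraries had 0 enriched windows, against 0 and 2 in the mixed ones. Abundant cytoplasmic mRNAs were higher in the mixed library relative to all genes in 20 of 20 cases for EED (median log2 ratio 1.22), EZH2 (2.09) and SUZ12 (0.78). Splicing factor transcripts were higher in 24 of 26, 22 of 26 and 25 of 26 cases, at percentiles of 99.8, 85.8 and 98.6 among random lists. The inputs of these pairs differ, with 57.3% of input reads in introns over listed windows for mixed EED and 16.9% for unmixed EED, so gene folds differ by input as well as by capture. XIST had its highest window at 800 to 900 in each no-mixing library, with folds of 0.368, 0.355 and 0.367. Across genes, folds of the mixed and unmixed library correlated at a Spearman value of 0.358 for EED, -0.15 for EZH2 and 0.816 for SUZ12. The EZH2 call ended with genes as the unit and among windows of at least 20 input reads, and on the table totals EZH2 turned around (0.205% against 0.230%) and SUZ12 lay below its no-mixing library (0.00320% against 0.0411%), while EED passed (0.0666% against 0.0427%).

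Genes enriched for 1 protein were set against those of another, to see whether different proteins captured the same RNAs. EED and EZH2 plus-tag CLIP shared 1158 genes, LENG8 and KDM5C among them, where 252 were expected of independent lists, a ratio of 4.60. EED and SUZ12 shared 2315 against 1848 (1.25), and EZH2 and SUZ12 1427 against 1155 (1.24). EED shared 2341 of its 2342 genes with SAFA CLIP (ratio 1.34) and 2340 of 2341 with PTBP1 CLIP (1.16). With SUZ12 it shared 2315 of 2341, and EZH2 shared 1427 of 1441 with SUZ12. These ratios are near the highest that the list sizes allow, so they cannot be ranked against 4.60. Minus-tag CLIP of EED and EZH2 shared 120 genes against 4.89 expected, a ratio of 24.5, with LENG8, MALAT1 and NEAT1 named in both. EED and SUZ12 minus-tag CLIP shared 362 against 61.6 (5.87). These were 362 of 366 EED genes, so 5.87 is near the highest that the list sizes allow and cannot be ranked against 24.5. PTBP1 and SAFA CLAP shared 10102 against 9164 (1.10). Transcript abundance was not matched in these expectations, and the plus-tag EED and SUZ12 ratio was 3.33 on the table totals and 1.01 with at least 10 sample reads. On the table totals EED had plus-tag ratios of 7.77 with EZH2, 3.70 with SAFA and 2.28 with PTBP1, EZH2 and SUZ12 had 3.06, and PTBP1 and SAFA CLAP had 2.09. Minus-tag ratios there were 8.71 for EED and EZH2, 8.88 for EED and SUZ12, and 24.9 for EZH2 and SUZ12 in place of 5.70, so which pair has the highest ratio depends on the scale. On the authors' scale EZH2 and SUZ12 shared 146 of 148 EZH2 genes. Their 5.70 is thus also near its highest and cannot be ranked against 24.5.

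In mouse cells, Spy-tagged PTBP1 was compared with Spy-tagged EED, EZH2, SUZ12 and YY1. It had 251 enriched windows in 96 genes, 97.2% of the windows intronic against 38.9% of its input reads over listed windows. The highest were in Tet2 (65.7, interval 18.1 to 544), Gabarapl2 (53.8), Snhg11 (46.3), Mid1 (37.5), Huwe1 (35.5), Macf1 (33.0), Cdh4 (28.8), Chd2 (25.2), Gab1 (23.3) and Kirrel (23.1). Among listed genes, Meis2 reached 12.6 and Hnrnpu 7.12. Hnrnpu also reached 4.41 in Spy-SUZ12 and 4.75 in Spy-YY1, at intron position 6000 to 6100 with 6 input reads. Its best window lay there in Spy-EED (0.331) and Spy-EZH2 (0.625) too, so a high Hnrnpu window was not particular to Spy-PTBP1. Spy-SUZ12 had 2 windows in Tsix (22.1, interval 6.07 to 183), which lies antisense to Xist and is uncertain, and Spy-YY1 had 1 in Sox2ot (6.88). Spy-EED and Spy-EZH2 had 0. No stem cell marker of the 12 listed held an enriched window for Spy-PTBP1. Its share of 0.0441% (0.0388% to 0.0499%) lay above all 4 other Spy-tagged proteins. Among windows of at least 20 input reads it was 0 in all of them. On the table totals, Spy-PTBP1 had 7402 enriched windows (1.30%) and Spy-SUZ12 2827 (0.676%). Spy-YY1 then had 2246 (0.641%), Spy-EED 201 and Spy-EZH2 203, so the near absence of calls in the other proteins depends on the scale.

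SPEN, which silences the inactive X chromosome together with Xist, had 64 enriched windows in 19 genes. Xist held 16, the highest at exon position 700 to 800 with a fold of 21.6 (interval 19.1 to 24.5) from 14004 reads. The fold over the first 3000 nt of Xist was 4.87 and after them 0.572. Map7d2 (18.7), Slc38a2 (13.6), Mid1 (11.1), Matr3 (10.7), Vdac1 (10.6), Ddx17 (8.14), Ddx5 (8.06), Pcbp2 (7.87) and Alg13 (7.74) followed. Of splicing factor transcripts 3 of 26 held an enriched window, of lncRNAs 1 of 12, and of stem cell markers 0 of 12. Malat1 and Neat1 stayed at best folds of 1.15 and 0.984. Windows of at least 20 input reads gave 39 calls, and folds set by the table totals gave 5538.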

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

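No test of this result was run, and it was singled out only after the values were seen. The mean fold of EZH2 plus-tag CLAP was 0.871 times that of EZH2 minus-tag CLAP, whereas the same ratio lay above 1 for EED (1.79), SUZ12 (2.74), PTBP1 (2.78) and SAFA (8.65). What drew attention is that EZH2 lay on the other side of 1 from the other 4 proteins under the same contrast. The direction turned among windows of at least 20 input reads, where the EZH2 mean fold was 0.135 with the tag (1447 windows) and 0.0517 without it (1012 windows), so it depends on which windows are used. It also rests on the authors' constants of 0.0885 and 0.188: before them, summed sample reads were above input reads with the tag (2016552 and 1339178) and below them without it (306207 and 376265). The difference between the proteins was not tested, since each table holds 1 sample column.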

How the results depend on the processing

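The settings chosen only after the results were seen are folds relative to the table totals, the tail including the observed count, windows of at least 20 input reads, the restriction to fully listed chromosomes, and, for the number of tables and the gene overlap, folds relative to the median window. A fold of 2, and leaving out small structured and ribosomal genes, kept every count by comparison and all 36 tables within 1.5 times. The fully listed chromosomes kept the CLIP tag contrast at 3 of 3 proteins. The tail including the observed count moved the gene overlap of EED and SUZ12 CLIP from 1.25 to 1.48 and SPEN from 64 to 56 windows, and left the counts of tables and proteins as they were.

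A fold of 5 gave 11 tables with at least 0.1% enriched windows in place of 12, 3 proteins with more in CLIP than in CLAP in place of 4, and 37 SPEN windows in place of 64. An unadjusted p below 1e-06 gave 11 tables and an overlap of 2.09, and an adjusted p below 0.05 an overlap of 1.09. With at least 10 sample reads there were 20 tables, 2 of 3 proteins above their minus-tag CLIP, 111 SPEN windows and an overlap of 1.01. With at least 20 these were 23 tables, 167 SPEN windows and an overlap of 1.03. Thinning gave 3 of 5 proteins above minus-tag CLAP in place of 2 and 7 of 12 above GFP in place of 6. The EZH2 calls behind both changes came without more enriched windows. Thinning raised shares, to 99.8% for PTBP1 CLAP and 99.1% for SAFA CLAP against minus-tag, 60.9% for CHTOP against GFP and 32.3% for SUZ12 CLIP against minus-tag. EZH2 plus-tag CLAP had 12 enriched windows of 223017 in place of 15 of 868199, but CHTOP had 192007 in place of 9552. Thinned to its CLAP total, SUZ12 CLIP had 31.6% with the deposited tail and 4.94% with the inclusive one, so thinned shares depend on the tail. Genes as the unit gave 17 tables, 19 SPEN genes and 0 of 3 proteins above no-mixing CLAP in place of 1.

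Folds relative to the median window gave 16 tables, 4 of 5 proteins above minus-tag CLAP, 2 of 3 above minus-tag CLIP, 3 of 6 with more in CLIP than in CLAP, 9 of 12 above GFP, 3 of 3 above no-mixing, 2599 SPEN windows and an overlap of 2.33. Folds relative to the table totals gave 20 tables, 5, 2, 2 and 11 proteins in the first 4 of those contrasts, 5538 SPEN windows and an overlap of 3.33. Windows of at least 20 input reads gave 17 tables, 2 of 3 proteins above minus-tag CLIP, 6 of 6 differing toward CLIP, 4 of 12 above GFP, 0 of 4 Spy contrasts in place of 4, 0 of 3 above no-mixing, 39 SPEN windows and an overlap of 2.04. That setting leaves out most windows, among them those on a low input minimum. Thinning left out windows that kept no read, and it raised the constant by the inverse of the share of reads kept. A single kept read could then give a high fold, so thinning can raise shares by itself. For the other moves the cause was not tested.

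Per table, the count of enriched windows stayed within 1.5 times in 32 of 36 tables at a fold of 5, 26 at an adjusted p below 0.05, 21 with the inclusive tail, 7 relative to the median window and 5 on the table totals. No paired analysis was possible because each table holds 1 sample column. For the same reason edgeR, DESeq2 and leave-one-out fits were not run, and thinning gave no value for SPEN or the overlap. Windows raised 5-fold can be missed in each simulated table: 48.0% were recovered in EZH2 CLAP, 17% in EZH2 CLIP and 79.0% in GFP CLAP, an order opposite to that of their read totals. These simulations set folds by the table totals, so they do not give the recovery on the authors' scale.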

Other observations

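The tests on CLIP against CLAP were chosen only after their result was seen, and the heat-shock genes were chosen after values of some of them were seen. Transcripts of the heat-shock response had their highest median folds in EZH2 plus-tag CLIP and CLAP, at 6.81 and 6.34 times the table mean. Of 19 such genes, 18 had more than 2 times the table's mean fold in EZH2 plus-tag CLIP and 14 of 18 measured did in CLAP. They took 2.55% of EZH2 plus-tag CLAP reads and 0.338% of its input reads, and 1.11% and 0.141% in CLIP. They were raised less in other tables, with medians of 1.98 in EED minus-tag CLIP, 1.91 in EED plus-tag CLIP, 1.80 in SAFA plus-tag CLAP, 1.72 in EED plus-tag CLAP (9 of 19 genes over 2) and 1.66 in EZH2 no-mixing CLAP. SUZ12 plus-tag CLIP had 0.810 and GFP CLAP 0.777.

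PTBP1 CLIP had 193 of 193 XIST exon windows enriched, against 105 in CLAP, with a best fold of 144 at position 12300 to 12400. SAFA CLIP had 182 of 193. The intronic share of enriched windows was 93.5% for EWSR1, 88.1% for CHTOP, 84.3% for SAFA plus-tag CLAP and 80.4% for SUZ12 plus-tag CLIP. Introns held 36.5%, 24.7%, 85.9% and 72.1% of their input reads over listed windows, so SAFA lay near its input. The share of enriched windows was 28.7% for EED plus-tag CLIP and about equal, at 15.2% and 15.1%, for EED and SUZ12 minus-tag CLIP. Their input reads were 81.5%, 82.6% and 75.1% intronic. The vault RNA VTRNA1-1 was enriched in its 1 listed window in PTBP1 plus-tag CLAP.

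EED, EZH2 and SUZ12 had far fewer enriched windows in plus-tag CLAP than in CLIP. A larger number of sample reads in CLIP was examined by thinning to the CLAP total, with the inclusive tail. CLIP stayed more than 1.5 times above CLAP for 3 of 3 proteins. It had 2125 enriched windows against 0 for EED, 2279 against 12 for EZH2 and 106473 against 2 for SUZ12. Thinning kept the authors' scale, where plus-tag CLAP mean folds were 0.103 for EED, 0.133 for EZH2 and 0.224 for SUZ12. Such folds leave few CLAP windows able to reach 3 at any depth, so thinning cannot separate read number from the constant. The authors' constant per table stays open, since with folds set by the table totals CLIP was above for 2 of 3 proteins, EED and SUZ12, and EZH2 turned around. That constant and the capture method cannot be told apart for EZH2, as how it was set is unknown. No biological explanation was tested.

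The heat-shock transcripts high for EZH2 may reflect the cells, the input or the capture. Their share of EZH2 plus-tag CLIP input was 0.966 times the median of the other plus-tag CLIP inputs. Those other shares ran from 0.0768% for PTBP1 to 0.283% for SUZ12, and 91.2% of listed EZH2 plus-tag CLIP windows lay on the input minimum. The share thus shows no sign of a low input or of more of these transcripts in the cells, but it cannot exclude either. Capture by tagged EZH2, or by a protein bound to it, was not tested and stays a hypothesis. EZH2 plus-tag CLAP at the authors' scale called HSPA6 and STIP1 alone. Halo-YY1 CLAP also had enriched windows on the co-chaperone gene DNAJB1.

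Of the 251 Spy-PTBP1 enriched windows, 250 were also listed in Spy-SUZ12 and in Spy-YY1, 98 in Spy-EED and 22 in Spy-EZH2. They took 1.90% of Spy-PTBP1 reads, 0.603% of Spy-SUZ12, 0.593% of Spy-YY1, 0.0914% of Spy-EED and 0.0407% of Spy-EZH2 reads. Low input shared by all Spy libraries was set against the number of these windows listed. With reads spread as in Spy-SUZ12, Spy-EED and Spy-EZH2 would list 239 and 241 of them, and they listed at most 0.41 times as many. Listing depends on sample reads, so a shared low input alone does not account for this difference between the libraries. Whether low input raised the folds at these windows is not decided by that count. Reads carried over from the Spy-PTBP1 library could contribute: the lower correlation across windows was 0.556, between the values set beforehand for and against it. No biological explanation was tested.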
